A study of Mus musculus with 8 samples.

How the data were processed

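Brown adipose tissue of 4 WT and 4 TG mice was profiled by RNA sequencing. Per the labels' protocols, tissue was frozen, RNA was taken up with TRIzol, and libraries were made from 1 ug of total RNA with an Illumina TruSeq RNA kit. Per the submitters' processing notes, the tools were bcl2fastq, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the genome build was mm10; their order, the strand setting and the annotation release are not given in the sources used here. The labels number the mice 1, 2, 3 and 5 in each group, and each column of the deposited table was matched to a mouse by that name. The design text gives 4 mice per group, so p-values measure the spread between mice. No batch, litter or day is given, and no sample was left out.

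The authors deposited FPKM, fragments scaled by gene length and by a divisor per library, for 54532 genes with a gene name, position, length and biotype per gene. How the authors obtained the divisor is not given in the sources used here. FPKM times gene length was a whole multiple of 1 step in every library, the largest distance from a whole number being 6.52e-09, so the reads behind each FPKM value were recovered by division. The recovered reads summed to 1.02 to 1.22 times the implied divisor in WT and 0.822 to 0.883 times in TG, so the authors' FPKM contain a scaling of the libraries beyond their total. Recovered reads served for depth, read shares and floors. The 95% binomial interval of a mitochondrial read share (exact Clopper-Pearson) was 28.98% to 29.03% for WT 1 and 6.903% to 6.926% for TG 1; intervals and floors cover counting error only. A floor is the level that 3 reads over a group would give. The table's gene identifiers were compared with the GENCODE M21 annotation of the same assembly, where 54495 were found, 98.3% of them at the same coordinates.

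Differences were tested with limma 3.58.1 in R 4.3.3 (eBayes with an intensity trend, two-sided) on log2(FPKM + 1) as deposited, for genes with at least 0.5 FPKM in at least 4 libraries, with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. The main test was not a count model, since the unit is FPKM. Single values were compared with exact permutation tests. The 38 gene lists and 20 cell type marker lists were fixed before the data were examined, and each with at least 3 measured members was tested with limma's camera at a preset correlation of 0.01, adjusted within each family. Camera with an estimated correlation and fry were run beside it. Of the marker lists 18 could be tested. "Adjusted over the list alone" means Benjamini-Hochberg over the members of that list.

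The genes named are Clcf1, the 10 with the largest rise and the 10 with the largest fall, and up to 4 members per list with the lowest p. The largest changes were taken among protein-coding genes past the threshold whose groups do not overlap and whose mean reaches 1 FPKM in the higher group, leaving out symbols of the form Gm with digits or ending in Rik. Any member of the gp130 receptor and mitochondrial DNA lists could be named as well. Genes outside this rule, such as those that make up a small count, were named after their values were seen. Some genes that belong to a count are not reported here by name. Counting could not separate reads of near-identical copies, overlapping genes or antisense partners, so values of mitochondrial genes with nuclear copies, haemoglobin, immunoglobulin and Serpina3 genes, and of genes with many processed pseudogenes, are uncertain.

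The procedure was tested on simulated data for this comparison, over 11913 genes. It recovered 36.7% of genes raised 2-fold, 82% of genes raised 4-fold, 52.3% of genes lowered to 0.5 and 85.4% of genes lowered to 0.25 of their level, with 6 false calls. All 5 lists of genes lowered 2-fold were called, and 0 of 20 lists of unchanged genes. Each gene was simulated independently, so this does not test how correlation between genes affects the list calls. The simulation also changed far fewer genes than were called in the data.

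Alternatives planned before the data were examined covered the pseudocount (0.1 and 0.01), the filter (none, or 5 FPKM), 4 scalings, 3 variance models, the thresholds, protein-coding genes alone, the replicate number as a block and leaving out each library. The scalings were upper quartile, trimmed mean of M values, quantile normalisation, and rescaling without mitochondrial, haemoglobin and the 20 most abundant genes. Added after seeing the data were division by all recovered reads, division by the reads outside the mitochondrial chromosome, limma's voom on the recovered reads, and leaving out WT 2 and TG 5. Nuclear copies of the mitochondrial messenger RNAs were sought with blastn 2.17.0 among the GENCODE M21 transcripts (at least 90% identity over at least 50% of the length). Figures were drawn with matplotlib 3.10.9.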

Results

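RNA from brown adipose tissue, the heat-producing fat of mice, was sequenced in 4 wild-type mice (WT) and 4 mice labelled as CLCF1-ATG transgenic (TG). CLCF1 is a cytokine of the interleukin-6 family, and its signal passes through the receptor chains encoded by Lifr and Il6st. The series title concerns heat production and the making of mitochondria, so the comparison asked which transcripts of brown fat differed between the genotypes and where the genes of both processes stood. The deposited table held FPKM for 54532 genes, of which 12508 reached at least 0.5 FPKM in at least 4 libraries and were tested. The reads recovered behind the FPKM values numbered 13734231 to 15751302 per WT library and 18494022 to 20183840 per TG library. Coordinates below are those of the deposited table, whose build is mm10 per the submitters' processing notes. Log2 changes are TG minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM.

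Clcf1 was measured first, since it checks the genotype labels. Clcf1 (ENSMUSG00000040663, chromosome 19, 4214238 to 4223490, plus strand) stood at 2.15 ± 1.28 FPKM in WT and 84.5 ± 4.75 FPKM in TG (SD, n = 4 each). The WT libraries ranged from 0.434 to 3.40 FPKM and the TG libraries from 78.7 to 89.9 FPKM, so all 8 libraries followed their labels. The difference gave p = 0.0286 in a two-sided exact permutation test over 70 assignments, the smallest p that 4 against 4 allow. In the limma fit of all genes the log2 change of Clcf1 was 4.87 (SE 0.297, adjusted p = 3.66e-06). The table gives 1 value per gene, so transcripts of the transgene and of the mouse's own Clcf1 are not separated in it.

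The genotypes differed across much of the transcriptome. With limma and Benjamini-Hochberg adjustment, 5513 genes passed an adjusted p of 0.05, of which 2788 were higher and 2725 lower in TG. These were 44.1% of the 12508 tested genes, and the list counts below are to be read against that share. At least 2-fold changes were found for 641 higher and 973 lower genes, and at least 8-fold changes for 37 higher and 43 lower genes. The 4 TG values lay wholly above or below the 4 WT values in 42.6% of the tested genes, against 2.86% by chance. Dividing by all recovered reads, a scaling chosen after seeing the data, raised the median log2 change of all genes from 0.01 to 0.32 and gave 5536 higher and 1442 lower genes. A planned rescaling without mitochondrial, haemoglobin and the 20 most abundant genes gave 5287 higher and 1546 lower genes.

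Wfdc21, a small secreted protein gene, was among the genes with the largest rise and went from 4.71 ± 1.72 to 1323 ± 272 FPKM (SD, n = 4 each; log2 change 7.88). Comp, a protein of cartilage matrix, rose by a log2 change of 7.25, Prtn3, a serine protease of neutrophil granules, by 6.17 and Cyp2f2, a cytochrome P450, by 5.95. Clu, an extracellular chaperone, rose from 12.4 ± 4.31 to 780 ± 80.5 FPKM, and the complement gene C4b from 28.5 ± 8.70 to 748 ± 128 FPKM. Lcn2, an iron-carrier binding protein of the acute phase, and Ffar2, a receptor for short-chain fatty acids, rose by 4.48 and 4.42. Reg1 had 0 reads in the WT libraries and 48.1 ± 18.1 FPKM in TG, which is at least 725-fold higher than the level that 3 reads over the WT group would give. All of these had adjusted p values of 2.56e-05 or lower in limma.

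Among the genes with the largest fall was Fabp3, a fatty acid carrier (ENSMUSG00000028773, chromosome 4, 130308595 to 130315463), which went from 1713 ± 663 to 21.4 ± 8.71 FPKM (SD, n = 4 each), a log2 change of -6.27 (SE 0.350, limma adjusted p = 2.17e-06). Cox7a1, a subunit of cytochrome c oxidase, fell by 4.52 on the log2 scale, Kng2 by 4.41, and Gmpr, a guanosine monophosphate reductase, by 4.39. Pank1, which makes the precursor of coenzyme A, fell by 4.19, and Slc27a2, an acyl-CoA synthetase that takes up fatty acids, by 4.04. The mitochondrial transcripts mt-Co3 and mt-Nd3 fell by 4.58 and 4.16, but both have nuclear copies with reads of their own, which makes their values uncertain.

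**Figure D1:**
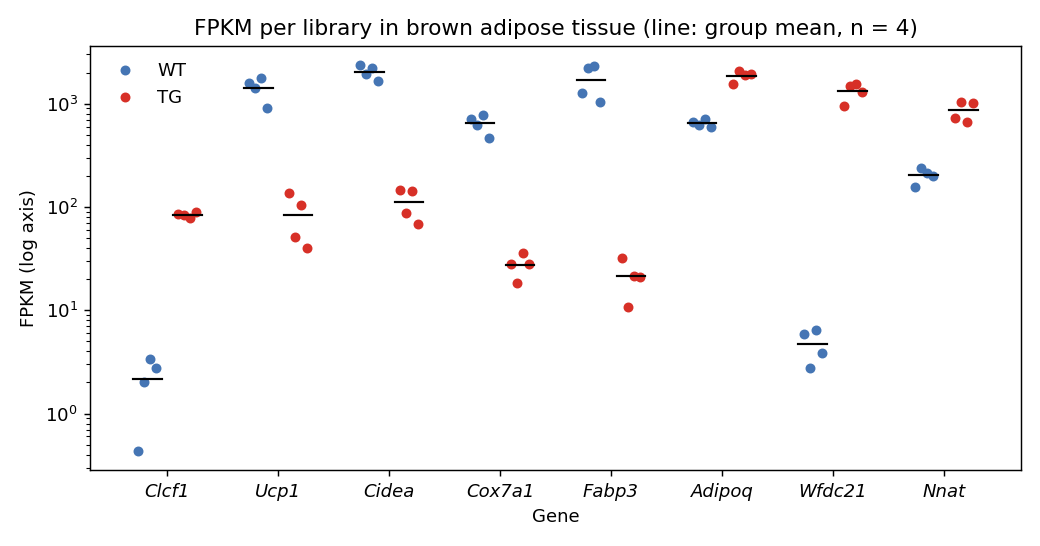
FPKM of 8 genes in each library on a log axis, with WT in blue, TG in red and a line at each group mean (n = 4). Clcf1, Adipoq, Wfdc21 and Nnat are higher in all 4 TG libraries, and Ucp1, Cidea, Cox7a1 and Fabp3 are lower in all 4, with Ucp1 at 1420 FPKM on average in WT and 82.8 FPKM in TG.

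Genes of the heat-producing programme were lower in TG. Ucp1, which uncouples respiration from ATP synthesis (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), fell from 1420 ± 371 to 82.8 ± 45.3 FPKM (SD, n = 4 each), a log2 change of -4.21 (SE 0.381, limma adjusted p = 2.90e-05). Cidea, a lipid droplet protein of brown fat, fell from 2031 ± 316 to 111 ± 39.5 FPKM, and Dio2, which activates thyroid hormone, from 21.8 ± 5.38 to 0.703 ± 0.305 FPKM. Of 30 measured thermogenic genes 20 fell, 2 rose and 8 did not pass, and the counts were the same adjusted over the list alone. The median log2 change was -1.35 (limma camera adjusted p = 1.77e-07, and adjusted p = 0.298 with an estimated correlation). The 2 that rose were the beta-3 adrenergic receptor gene Adrb3 (log2 change 0.69) and the brown lineage factor Ebf2 (0.40), both named after their values were seen; the call of Ebf2 was lost without WT 2 and TG 5 (adjusted p = 0.0798, the highest over its alternatives). Of 10 brown adipocyte markers 7 fell, 1 rose and 2 did not pass, with a median of -2.77 (camera adjusted p = 0.000780, and adjusted p = 0.356 with an estimated correlation). All 10 of these markers are also on the thermogenic list, so they are not separate evidence. Among them Kcnk3, a potassium channel, fell by 2.47.

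Genes enriched in white fat were higher in TG. Of 18 measured members 13 rose, 1 fell and 4 did not pass, Fgf1 being the gene that fell (log2 change -1.50), with the same counts adjusted over the list alone and a median log2 change of 1.29 (camera adjusted p = 3.92e-05, and adjusted p = 0.298 with an estimated correlation). The matrix gene Dpt rose from 109 ± 18.8 to 501 ± 36.9 FPKM (SD, n = 4 each), Ccdc80 by a log2 change of 2.26 and the acute-phase gene Hp by 2.48. Hp is also on the list of STAT3 targets below. Nnat rose by 2.07, and the hormone genes Retn and Lep by 1.80 and 1.52. Genes shared by all adipocytes did not fall: 7 of 10 rose and 3 did not pass, with a median log2 change of 0.76 (camera adjusted p = 0.00614, and adjusted p = 0.356 with an estimated correlation). Adipoq, which encodes adiponectin, rose from 650 ± 50.4 to 1864 ± 220 FPKM, and Cfd, which encodes adipsin, rose by 2.34.

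Transcripts encoded on mitochondrial DNA were lower in TG, and so was their share of the library. Reads on the mitochondrial chromosome made up 29.4% ± 5.78 of the recovered reads in WT and 6.87% ± 0.547 in TG (SD, n = 4 each; two-sided exact permutation p = 0.0286, the smallest possible). All 13 messenger RNAs of mitochondrial DNA fell, with the same count adjusted over the list alone and a median log2 change of -2.34 (camera adjusted p = 1.55e-09, and adjusted p = 0.298 with an estimated correlation). mt-Nd5, a subunit of complex I, fell by 1.70 and mt-Atp6, a subunit of ATP synthase, by 4.04; mt-Atp6 also has a nuclear copy with many reads. With no filter on low values 11 of the 13 passed, and with quantile normalisation 12.

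**Figure D2:**
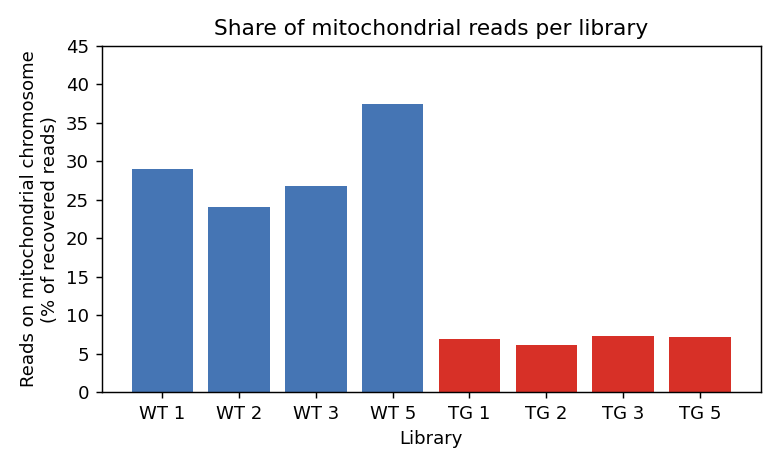
Reads on the mitochondrial chromosome as a percentage of all recovered reads, 1 bar per library, WT in blue and TG in red. The WT libraries range from 24.1% to 37.5% and the TG libraries from 6.09% to 7.34%.

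Nuclear genes of the respiratory chain fell almost together. Over the 4 lists of complexes I to V, 79 of 84 measured genes fell, 0 rose and 5 did not pass (Atp5g1, Atp5g3, Atp5j, Atpif1 and Cox6a2), with a median log2 change of -1.75. Of these 5, Atp5g1 was called higher without WT library 2 (limma adjusted p = 0.000373) and Atp5j lower without TG library 3 (0.0431), and the adjusted p over the alternatives ran from 0.000373 to 0.244 and from 0.0431 to 0.512. Atp5g3 was called higher with quantile normalisation (adjusted p = 0.000515), the rescaling without abundant genes (0.00118) and division by all recovered reads (0.00164), its range being 0.000515 to 0.431. Atp5g1 was also called higher with that rescaling (0.0135) and that division (0.0140). The same held for Atp5g1 with a filter of 5 FPKM (0.0470), with voom (0.0292) and without WT 2 and TG 5 (0.00164). In complex I all 37 members fell (median -1.74), with Ndufs6 going from 371 ± 49.5 to 57.4 ± 11.8 FPKM (SD, n = 4 each) and Ndufb7 falling by 2.28. In complexes II and III all 13 fell (median -1.85), among them Cyc1 by 2.25 and Uqcr11 by 2.39. In complex IV 16 of 17 fell (median -1.87), with Cox8b going from 4297 ± 640 to 520 ± 141 FPKM and Cox5b falling by 2.34. Cox7a1 and Cox8b are also on the thermogenic list. In complex V 13 of 17 fell (median -1.45), among them Atp5d by 2.48 and Atp5o by 1.91. Adjusted over the list alone, the counts were the same except that 1 member of complex V rose. The camera adjusted p values ran from 9.39e-21 for complex I to 2.14e-06 for complex V. With an estimated correlation they were adjusted p = 0.298 for complexes I to IV and adjusted p = 0.350 for complex V.

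Other parts of the mitochondrion were lower as well. In the tricarboxylic acid cycle 21 of 23 genes fell, 1 rose and 1 did not pass, with a median log2 change of -1.50 (camera adjusted p = 6.14e-10, and adjusted p = 0.374 with an estimated correlation). The gene that rose was Pcx (log2 change 0.86), pyruvate carboxylase, and Suclg2 did not pass. Sdha, Sdhb, Sdhc and Sdhd are on this list and on that of complexes II and III, so their falls are counted in both. Suclg1, a subunit of succinyl-CoA ligase, went from 315 ± 53.6 to 37.9 ± 3.99 FPKM (SD, n = 4 each). In fatty acid oxidation 16 of 25 fell, 2 rose and 7 did not pass, with a median of -1.06 (camera adjusted p = 1.63e-05, and adjusted p = 0.429 with an estimated correlation), with Cpt1a, the liver-type carnitine transferase, among those that rose (0.78). Acaa2, the thiolase of the last step of the cycle, went from 2347 ± 334 to 204 ± 33.3 FPKM, and Hadhb, a subunit of the trifunctional protein, fell by 2.51. The mitochondrial ribosome showed smaller falls, with 49 of 77 lower, 0 higher and 28 not passing (median -0.62, camera adjusted p = 1.51e-12, and adjusted p = 0.439 with an estimated correlation). This list was drawn by gene symbol alone, so membership does not show that a gene encodes a ribosomal protein. On it Mrps36 fell by 2.30 and Mrps9 by 1.35. Import proteins had 17 of 28 lower, 0 higher and 11 not passing (median -0.61, camera adjusted p = 2.26e-06, and adjusted p = 0.441 with an estimated correlation), with Timm13 down by 1.76. Adjusted over the list alone, fatty acid oxidation had 18 lower and 3 higher, the mitochondrial ribosome 53 lower and import 19 lower, while the cycle had the same counts.

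Regulators of mitochondrial biogenesis moved in both directions. Of 33 measured genes 10 fell, 5 rose and 18 did not pass (11 fell and 5 rose adjusted over the list alone). The list was not called by camera (median 0.01, mean -0.23, test direction down, adjusted p = 0.291), and its median and test differ in sign. Ppargc1b, a coactivator of mitochondrial genes, fell from 4.46 ± 0.766 to 0.702 ± 0.131 FPKM (SD, n = 4 each). The muscle-type regulator Perm1 fell by 2.82, and the estrogen-related receptors Esrra and Esrrg by 1.17 and 0.946. Ppargc1a, named after its value was seen, had a log2 change of -0.63 (SE 0.184, limma adjusted p = 0.0203). Its call was lost without WT library 3 (adjusted p = 0.0514), without TG library 1 (0.0580) and with no filter (0.0559), and with division by all recovered reads (0.168) and the rescaling without abundant genes (0.104). Over its alternatives the adjusted p of Ppargc1a ran from 0.0104 to 0.168. Ppargc1a, Ppargc1b, Esrra and Esrrg are also on the thermogenic list, so their falls are counted in both. Tfb1m (0.74), Nos3 (0.82), Camkk2 (0.47), Prkaa2 (0.40) and Foxo1 (0.37) were those that rose. The call of Nos3 was lost without WT 2 (adjusted p = 0.0540), WT 3 (0.0529), TG 2 (0.0587) or TG 3 (0.0511), and that of Prkaa2 without TG 3 (0.0651) or TG 5 (0.0645); over all alternatives the adjusted p reached 0.0985 and 0.0827. Tfam, the packaging factor of mitochondrial DNA, also named after its value was seen, stood at 7.67 ± 2.34 FPKM in WT and 8.35 ± 0.580 FPKM in TG (adjusted p = 0.557); with the rescaling without abundant genes it was called higher (log2 change 0.49, adjusted p = 0.0421, with a range of 0.0421 to 0.797 over its alternatives).

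Parts of the CLCF1 receptor system changed and others did not pass the test. Lifr rose by 0.446 on the log2 scale, while Cntfr, the ligand-binding chain, and the kinase gene Jak2 fell by 0.828 and 1.08. Il6st stood at 11.6 ± 1.44 FPKM in WT and 11.2 ± 2.12 FPKM in TG (SD, n = 4 each; limma adjusted p = 0.806). Over the list 4 of 12 rose, Clcf1 and Il11ra1 among them, 2 fell and 6 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.252). The call of Il11ra1 was lost without TG library 5 (adjusted p = 0.0563), without WT 2 and TG 5 (0.0918) and with the replicate block (0.05004), with a range of 0.000473 to 0.0918 over its alternatives. The call of Cntfr was lost with division by all recovered reads (adjusted p = 0.0988), with the rescaling without abundant genes (0.0519) and without WT 2 and TG 5 (0.0546), and over its alternatives ran from 0.000580 to 0.0988.

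Target genes of STAT3, the transcription factor downstream of gp130, moved in both directions. Of 34 measured genes 8 rose, 10 fell and 16 did not pass (9 rose and 13 fell adjusted over the list alone), and the list was not called (median -0.25, mean 0.13, camera direction down, adjusted p = 0.708). The acute-phase gene Lbp went from 1.64 ± 0.423 to 18.3 ± 3.65 FPKM (SD, n = 4 each) and Serpina3m rose by 3.56, with the close paralog Serpina3n at 4.04. Lcn2 and Hp, given above, are also on this list and rose by 4.48 and 2.48, Hp being on the white fat list as well. Cish, a feedback inhibitor of cytokine receptors, fell by 2.26. Socs3, another feedback inhibitor, stood at 17.2 ± 8.29 FPKM in WT and 13.03 ± 5.07 FPKM in TG (limma adjusted p = 0.664), and WT library 1 decided that outcome, since without it the adjusted p was 0.0447 with a log2 change of -0.74, the range over its alternatives being 0.0447 to 0.926. Stat3 itself stood at 18.7 ± 5.62 and 20.7 ± 1.83 FPKM (adjusted p = 0.493), and was called higher with division by all recovered reads (log2 change 0.59, adjusted p = 0.0334, with a range of 0.0334 to 0.894 over its alternatives). Serpina3n, Cish, Socs3 and Stat3 were named after their values were seen.

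Lipid handling showed opposite changes among neighbouring genes. Of 22 genes of lipid uptake and storage 9 rose, 6 fell and 7 did not pass, and the list was not called (median 0.16, mean -0.11, camera direction up, adjusted p = 0.617). Its lowest member was Fabp3, given above, at a log2 change of -6.27. The droplet coat genes Plin4 and Cidec rose by 2.05 and 1.52, while Plin2 fell from 551 ± 175 to 187 ± 16.7 FPKM (SD, n = 4 each). In lipolysis 6 of 14 rose, 2 fell and 6 did not pass (camera adjusted p = 0.440); Plin1 rose by 1.25 and Pde3b by 1.28, whereas Plin5, the coat protein of oxidative tissue, fell by 1.75 and Aqp7, a glycerol channel, by 0.55. The call of Aqp7 was lost with division by all recovered reads (adjusted p = 0.518, the highest over its alternatives). In fatty acid synthesis 2 of 18 rose, 5 fell and 11 did not pass (camera adjusted p = 0.495), with Srebf1 up by 2.39, Insig1 by 1.24 and Elovl6, Mlxipl, Acacb, Fads1 and Fads2 down, Elovl6 by 2.47 and Mlxipl by 1.54. Fads2 lost its call without any of the libraries but WT 3 (adjusted p 0.0558 to 0.109), and Fads1 with the rescaling without abundant genes (0.0904) and with division by all recovered reads (0.104). Adjusted over the list alone, lipolysis had 3 lower and the other counts were the same. Glucose uptake and glycolysis had 16 of 25 lower, 1 higher and 8 not passing (median -0.96, camera adjusted p = 3.77e-05, and adjusted p = 0.298 with an estimated correlation; 16 lower and 2 higher adjusted over the list alone). Pdk3 rose by 0.89. Pkm fell from 297 ± 47.9 to 70.6 ± 13.4 FPKM and Ldhb by 2.40.

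**Figure D3:**
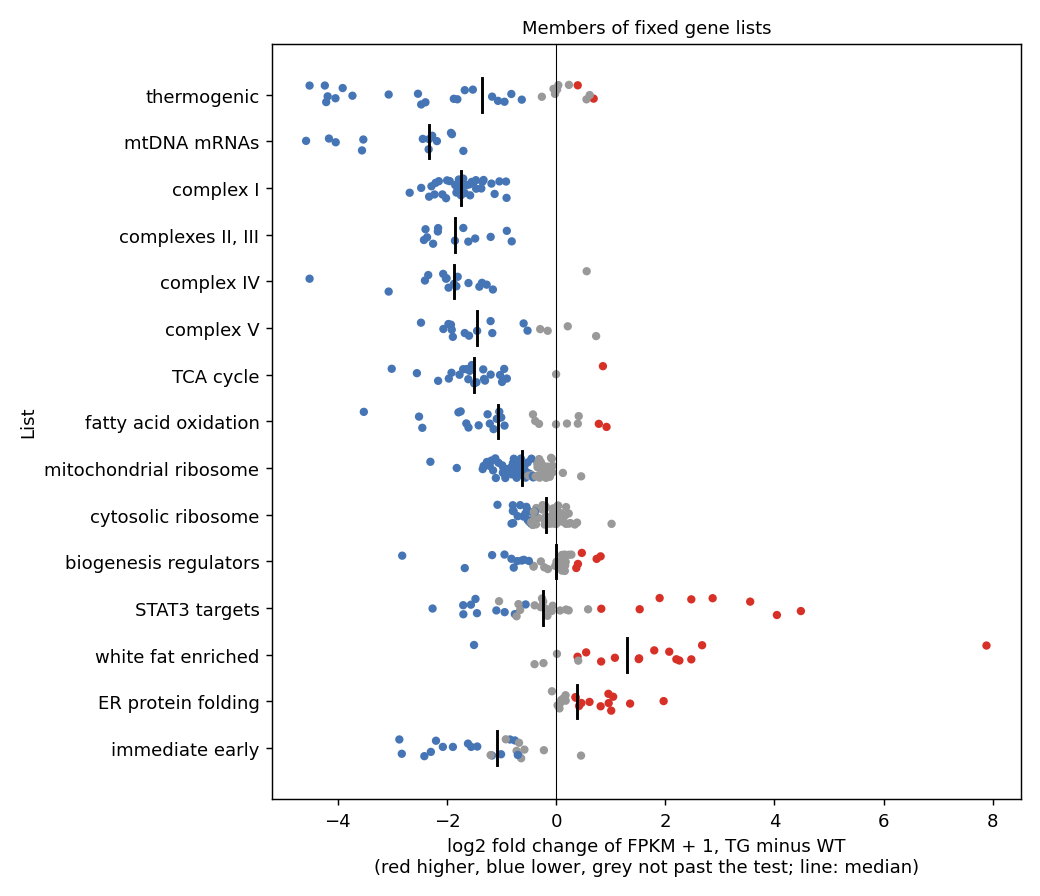
Log2 fold changes, TG minus WT, of the measured members of 15 gene lists fixed before the data were examined, 1 point per gene, with red for higher, blue for lower, grey for genes not past the test and a line at each median. The medians are -1.35 for thermogenic genes, -2.34 for mitochondrial DNA messenger RNAs and 1.29 for white fat genes; that of the cytosolic ribosome is -0.19 and turns positive with quantile normalisation, with division by all recovered reads and with the rescaling without abundant genes.

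Over all 38 gene lists tested, camera called 22, of which 5 were higher and 17 lower. With an estimated correlation limma camera called 0, the lowest adjusted p being 0.298, and 4 lists had an unadjusted p under 0.05. With fry, which asks whether a list's genes move in the same direction without comparing them with other genes, 27 lists were called.

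Markers of other cell types moved with genotype as well, beside the changes in brown and white fat genes. All 11 measured endothelial markers fell, with a median log2 change of -1.77 (camera adjusted p = 7.54e-05, and adjusted p = 0.356 with an estimated correlation); Cldn5, a tight junction gene, went from 104 ± 47.5 to 13.6 ± 3.46 FPKM (SD, n = 4 each) and Pecam1 fell by 1.80. All 5 erythroid genes fell (median -2.21, camera adjusted p = 0.00254, and adjusted p = 0.356 with an estimated correlation), and haemoglobin reads made up 0.586% ± 0.213 of the recovered reads in WT and 0.160% ± 0.0171 in TG (two-sided exact permutation p = 0.0286). Of 5 cardiac or smooth muscle markers 4 fell, Acta2, Myl9, Cnn1 and Myh11, and 1 did not pass (median -1.26, camera adjusted p = 0.0266, and adjusted p = 0.356 with an estimated correlation), with Acta2 down by 2.07. Plasma cell markers had 4 of 5 higher, Igkc, Jchain, Mzb1 and Xbp1, and 1 not passing (median 1.51, camera adjusted p = 0.0211, and adjusted p = 0.356 with an estimated correlation); Jchain rose from 2.002 ± 0.416 to 26.2 ± 5.97 FPKM and the immunoglobulin gene Igkc by 3.76. The plasma cell call was lost with division by all recovered reads (adjusted p = 0.0858) and with the rescaling without abundant genes (0.0926), and that of cardiac or smooth muscle with a filter of 5 FPKM (0.17998); over the alternatives the adjusted p ran from 0.000310 to 0.356 and from 0.000926 to 0.356. B cell markers had 3 of 4 higher, Ighm, Ighd and Cd79b, and 1 not passing (median 1.58, camera adjusted p = 0.0364, and adjusted p = 0.356 with an estimated correlation). White adipocyte markers had 5 of 7 higher, Lep, Nnat, Retn, Agt and Hoxc8, and 2 not passing (median 1.08, camera adjusted p = 0.0364, and adjusted p = 0.356 with an estimated correlation). All of these markers are also on the list of genes enriched in white fat, so they are not separate evidence. The calls of the B cell and white adipocyte lists were lost without WT library 1, at adjusted p = 0.0549 for both, with the rescaling without abundant genes (0.184 and 0.128), with division by all recovered reads (0.177 and 0.132) and with array weights (0.0908 and 0.0759). The B cell call was also lost with upper quartile scaling (0.0534), quantile normalisation (0.0631) and voom (0.108), and the white adipocyte call with a filter of 5 FPKM (0.0537). Over the alternatives the adjusted p ran from 0.000578 to 0.356 for B cells and from 0.000504 to 0.356 for white adipocytes. Agt lost its call without WT 3, TG 1, TG 3 or TG 5 (adjusted p 0.0502 to 0.0604) and Ighd without TG 1, TG 2 or TG 3 (0.0515 to 0.0534). TG 5 lay within the WT range for Ighd (0.276 FPKM) and Cd79b (0.823 FPKM), while TG 1, TG 2 and TG 3 stood at 4.31 to 6.19 FPKM and 4.32 to 6.09 FPKM.

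Other cell types were not called. Mural cells had 5 of 7 markers lower, 1 higher and 1 not passing (camera adjusted p = 0.228), with Rgs5 down by 2.11 and Cspg4 up by 1.88. Macrophage markers had 5 of 16 higher (Mrc1, Cd163, Csf1r, Lyz2 and Adgre1), 4 lower (Cd9, Trem2, Gpnmb and Itgax) and 7 not passing (camera adjusted p = 0.924); Mrc1 rose by 1.07 and Cd9 fell by 1.26. Of these, Adgre1 lost its call without WT 2, WT 3, TG 1, TG 2 or TG 3 (adjusted p 0.0547 to 0.0592), Itgax without WT 2, WT 3, WT 5, TG 2, TG 3 or TG 5 (0.0642 to 0.103), Csf1r without TG 1 (0.0548) and Lyz2 without TG 5 (0.0537). Gpnmb lost its call with the rescaling without abundant genes (0.115) and with division by all recovered reads (0.121), and Cd163 without WT 2 and TG 5 (0.0524). Progenitor and fibroblast markers had 3 of 13 higher (Gsn, Col3a1 and Col1a1), 2 lower (Ly6a and Pdgfra) and 8 not passing (camera adjusted p = 0.399); Pdgfra lost its call without WT 1, TG 2, TG 3 or TG 5 (0.0537 to 0.0798). T and NK cell markers had 5 of 9 higher (Trbc2, Nkg7, Cd3d, Lck and Cd8b1) and 4 not passing (median 0.67, camera adjusted p = 0.0583), and this list was called without TG library 5 (adjusted p = 0.00154), without WT library 5 (0.0259), without WT 2 and TG 5 (0.00170) and with no filter (0.00379), with a range of 0.00154 to 0.712 over its alternatives. Nkg7, Cd3d, Lck and Cd8b1 each lost their call without any of WT 1, 2 or 3 and TG 1, 2 or 3 (adjusted p 0.0594 to 0.107). TG 5 lay within the WT range for Nkg7 (0.764 FPKM), Cd3d (0.481 FPKM) and Lck (0.387 FPKM). None of 14 skeletal muscle genes passed the limma test, at an unadjusted p under 0.05 either, and their summed FPKM was highest in WT 2 (4197 FPKM) and TG 5 (2362 FPKM). Without these libraries, an alternative chosen after seeing the data, 4091 genes passed, 2018 higher and 2073 lower, and camera called 22 gene lists and 9 marker lists. Adjusted over the list alone, macrophages had 5 lower, T and NK cells 6 higher, B cells 4 higher and plasma cells 1 lower, and the other marker counts were the same. Over the 18 marker lists tested camera called 8, of which 4 were higher and 4 lower; with an estimated correlation limma camera called 0, with 2 at an unadjusted p under 0.05, and fry called 9.

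**Figure D4:**
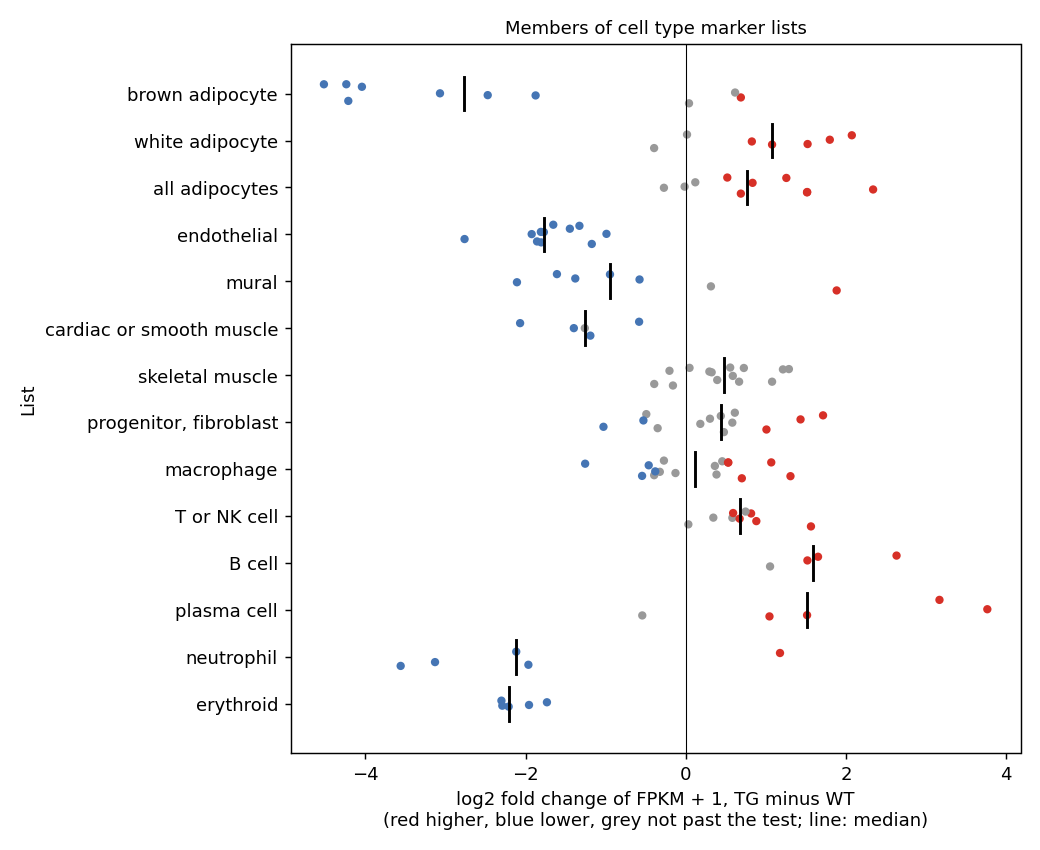
Log2 fold changes, TG minus WT, of the measured members of 14 cell type marker lists, 1 point per gene, with red for higher, blue for lower, grey for genes not past the test and a line at each median. The endothelial median is -1.77 and the plasma cell median 1.51, while no skeletal muscle marker passed the test.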

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

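The tests of library scaling, nuclear copies, transcript length and dilution of other cell types below were chosen after the results they bear on were seen. The limma comparison called 5513 genes. Of the 35 splits of the 8 libraries into 4 and 4, the real one alone gave as many and the highest of the others gave 1. All other splits mix the genotypes, which widens the spread within groups, so few calls were to be expected there. The real split was the most extreme of the 35, the smallest share this test can reach. A batch that follows genotype would give the same result.

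Transcripts of mitochondrial proteins were lower in TG, whether encoded in mitochondrial DNA or in the nucleus. The authors' scaling was tested as the whole cause: over 6 other scalings the least negative median log2 change was -1.21, for the nuclear respiratory chain genes under quantile normalisation. Reads shared with nuclear copies would spare genes without one. However, the 8 messenger RNAs with no copy of 100 FPKM or more had a median of -2.26 against -4.04 for the 5 with one. For mt-Nd1, mt-Nd2 and mt-Atp8 no copy was found among annotated transcripts, and they stood at -2.44, -2.33 and -3.53. The change of mt-Atp8 was close to that of mt-Co2 (-3.56), which has a copy, so shared reads cannot be excluded for mt-Atp8. Shared reads may still add to the fall of genes with a copy, which among the 8 include mt-Nd4l (copy at 61.5 FPKM) and mt-Co1 (22.4 FPKM). A loss of short transcripts would lower other genes of that length, but 84 genes matched to the respiratory chain genes on length and level had a median of -0.10. These tests argue against each as the whole cause. A difference in library content that follows genotype was not tested for these transcripts and stays open, as recovered reads per library did not overlap between the groups. An effect of the transgene, fewer mitochondria per cell or a change in the makeup of the pad stay open as hypotheses, the last taken up next.

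Brown fat genes were lower and white fat genes higher in TG, and tissue sampling is a candidate explanation. Tissue of a posterior white depot brings Hoxc9 and Hoxc10, which had 0 reads in the TG libraries, allowing at most 0.0173 FPKM; Hoxc8 and Hoxc6, which go with that explanation, were higher in TG, at 1.21 to 1.97 against 3.64 to 5.59 FPKM and 0.943 to 1.82 against 2.46 to 3.54 FPKM, and the planned bound of 0.5 FPKM for Hoxc8 was unusable because WT brown fat already passed it. White fat attached to the pad that replaced the brown adipocytes would lower the brown lineage genes Zic1, Lhx8, Prdm16 and Ebf2 with Ucp1, but their median log2 change with a pseudocount of 0.1 was 0.29. The lineage genes had WT means of 0.580 to 2.62 FPKM. If their reads came from brown adipocytes, these genes argue against a replacement as large as the fall of Ucp1. Which cells the reads came from was not tested. A smaller share of attached white fat stays open, since these lineage genes are low. The rule set beforehand needed Hoxc8, Hoxc9 and Hoxc10 each under 0.5 FPKM in TG, so by that rule the depot test was undecided. Hoxc9 and Hoxc10 speak against a posterior depot and Hoxc8 and Hoxc6 for it, so that explanation is left undecided. A change of the brown adipocytes themselves under the transgene is the biological hypothesis that the design names, and these data do not separate it from a shift between cell types.

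Endothelial markers were lower in TG, and a larger share of adipocyte RNA could dilute all other cells. It would lower the markers of the other cell types alike, but the medians of 6 lists, from endothelial to B cell, lay 3.36 apart on the log2 scale, with 4 of them above 0. This argues against dilution alone, and fewer vessels, less blood in the tissue or lower marker expression per cell stay open and were not tested.

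A gap test that marks about 1 in 20 groups by chance found single libraries far from the other 3 of their group in 21 of 361 groups, against 18.05 by chance. In FPKM, WT 1 stood apart for Socs3 (4.87), Esrra (53.0) and Pdgfra (3.34), WT 2 for Atp5g1 (9.06) and Cox6a2 (82.4), and WT 5 for mt-Nd3 (4835), Cfd (5424) and Pdk3 (1.71). TG 1 stood apart for Lcn2 (66.8), Camkk2 (4.01), Akt1 (19.2) and Col1a1 (33.4), TG 2 for Adrb3 (108.2) and Ddit3 (8.93), and TG 3 for Ndufs6 (75.01). TG 5 stood apart for Gmpr (2.80), Perm1 (0.660) and Cox6a2 (35.9). The summed FPKM of skeletal muscle genes was 4197 in WT 2, with 47.0 to 467 in the other WT libraries, and 2362 in TG 5, with 252 to 463 in the other TG libraries. WT 3 had 15751302 recovered reads, the most in its group.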

How the results depend on the processing

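Division by all recovered reads, division by reads outside the mitochondrial chromosome, voom and leaving out WT 2 and TG 5 were chosen after the data were seen. The cause of a change below was not tested unless given. A filter of 5 FPKM, which tests fewer genes, gave 3148 genes, 1445 higher and 1703 lower, and a 2-fold threshold, stricter by construction, gave 1614, 641 and 973. The rescaling without abundant genes gave 5287 higher and 1546 lower, and division by all recovered reads 5536 and 1442, as these raised the median log2 change of all genes to 0.28 and 0.32; the higher genes were 50.6%, 77.4% and 79.3% of those called as deposited, rescaled and divided. Camera called 5 marker lists with the 5 FPKM filter, 5 with the rescaling and 5 with that division. With an estimated correlation it called 0 gene lists and 0 marker lists; the medians are as before (thermogenic -1.35, complex I -1.74, II and III -1.85, IV -1.87, V -1.45, mitochondrial DNA -2.34, white fat 1.29), since only the test differs. Mitochondrial biogenesis was called lower by fry, against the sign of its median (0.00653, adjusted p = 0.0199, with a range of 0.0199 to 0.599). The cytosolic ribosome turned from -0.19 to 0.27 with quantile normalisation (adjusted p = 0.00384). Suclg2, which did not pass as deposited, was higher with the rescaling (0.36) and with division by all reads (0.41), and Adipor1, lower as deposited, stood at 0.0410 with that division.

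Leaving out each library gave 4569 to 5562 genes (2278 to 2743 higher, 2291 to 2819 lower), 21 to 22 gene lists, 6 to 9 marker lists and a log2 change of Clcf1 of 4.53 to 5.07. The medians ranged from -1.39 to -1.32 for thermogenic genes, -2.49 to -2.21 for mitochondrial DNA, -1.87 to -1.67, -1.99 to -1.70, -2.02 to -1.78 and -1.58 to -1.32 for complexes I, II and III, IV and V, 1.19 to 1.36 for white fat and -0.07 to 0.05 for biogenesis. The replicate number as a replicate block gave 4847 genes (2389 higher, 2458 lower), 22 gene lists and 8 marker lists. Libraries of the same number correlated at -0.190, -0.173, 0.0373 and -0.238 in their deviations, and none correlated best with its own number. These values show no pairing in expression but cannot exclude a shared litter or day, which the labels do not give. Of 176 named genes besides Clcf1, 136 kept direction and call in every alternative run for them; of 4179 comparisons 195 lost a call, 13 gained one and 3 turned direction. Of 56 lists 14 kept both, and of 1449 comparisons 57 lost a call, 30 of them with an estimated correlation, 15 gained one and 1 turned. With about 13734231 reads or more per library, genes near 0.5 FPKM rest on few reads, which limits their precision.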

Other observations

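Division by all recovered reads and leaving out WT 2 and TG 5 were chosen after the data were seen, and the test of RNA without a poly(A) tail was set before its result. Of 20 genes of protein folding in the endoplasmic reticulum 12 rose in TG, 0 fell and 8 did not pass in limma (median log2 change 0.39, camera adjusted p = 0.000334, and adjusted p = 0.340 with an estimated correlation); Pdia4 went from 11.03 ± 1.55 to 45.9 ± 3.92 FPKM (SD, n = 4 each) and Edem1 rose by 1.36. Plasma cell markers rose alongside, 4 of 5 with a median of 1.51 and Xbp1 (1.04) on both lists, so the cells in which folding genes rose are left open. Of 18 genes of insulin and adipokine signalling 10 rose, 3 fell (Igfbp3, Akt1 and Adipor1) and 5 did not pass (median 0.43, camera adjusted p = 0.00871, and adjusted p = 0.298 with an estimated correlation), with Igf1 up by 2.06 and Insr by 1.21. The calls of Akt1 and Adipor1 were lost with division by all recovered reads (adjusted p = 0.988 and 0.769), with the rescaling without abundant genes (0.734 and 0.953) and without WT 2 and TG 5 (0.0552 and 0.0568), Adipor1 standing at a log2 change of 0.04 with that division; the lowest over their alternatives were 0.00203 and 0.00882. Adipogenic regulators had 12 of 18 higher, 2 lower (Cebpb and Hlx) and 4 not passing (median 0.48, camera adjusted p = 0.00196, and adjusted p = 0.298 with an estimated correlation), with Klf15 going from 3.99 ± 1.26 to 36.8 ± 2.45 FPKM. Matrix genes had 15 of 34 higher, 4 lower and 15 not passing (median 0.52, camera adjusted p = 0.0171, and adjusted p = 0.599 with an estimated correlation); Col15a1 rose by 2.09, and Thbs1, Timp1, Tnc and Postn were the 4 that fell. The matrix call was lost with the rescaling without abundant genes (adjusted p = 0.178) and with division by all recovered reads (0.127), within a range of 0.00275 to 0.599 over its alternatives. The serine pathway genes Psat1 and Phgdh rose by 2.34 and 1.88 while Ddit3 fell by 1.02, and the integrated stress response list had 6 higher, 8 lower and 9 not passing (camera adjusted p = 0.869).

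Of 24 immediate early genes 15 fell in TG, 0 rose and 9 did not pass in limma (median log2 change -1.09, camera adjusted p = 6.38e-06, and adjusted p = 0.441 with an estimated correlation); Maff went from 48.2 ± 28.5 to 7.74 ± 3.34 FPKM (SD, n = 4 each) and Nr4a3 fell by 1.89. Vascular growth genes had 13 of 17 lower, 2 higher and 2 not passing (median -1.33, camera adjusted p = 0.00107, and adjusted p = 0.298 with an estimated correlation), with Pdgfb down by 1.82 and Angpt1 and Hgf as the 2 that rose. All 11 endothelial markers fell too (median -1.77) and some of them belong to both lists, so this list does not separate a change in growth signals from less endothelial RNA. Hypoxia genes had 9 of 16 lower, 1 higher (Bnip3) and 6 not passing (median -0.46, camera adjusted p = 0.0210, and adjusted p = 0.378 with an estimated correlation), and the call was lost with a filter of 5 FPKM (adjusted p = 0.260, with a range of 0.00275 to 0.378 over its alternatives). Mitochondrial chaperones and proteases had 10 of 14 lower, 2 higher (Yme1l1 and Htra2) and 2 not passing (median -0.92, camera adjusted p = 0.000523, and adjusted p = 0.446 with an estimated correlation). Fission and fusion genes had 8 of 12 lower, 1 higher (Yme1l1) and 3 not passing (median -0.35, camera adjusted p = 0.00621, and adjusted p = 0.397 with an estimated correlation); the call was lost with the rescaling without abundant genes (median -0.02, adjusted p = 0.0528) and with division by all recovered reads (median 0.03, adjusted p = 0.0698, with a range of 0.000484 to 0.397 over its alternatives). The cytosolic ribosome had 19 of 79 lower, 0 higher and 60 not passing (median -0.19, camera adjusted p = 0.0109, and adjusted p = 0.816 with an estimated correlation); its median turned positive with quantile normalisation (0.27), the rescaling without abundant genes (0.19) and division by all recovered reads (0.24), and its call was lost without WT library 5 (adjusted p = 0.108) and without TG library 1 (0.177), with a range of 0.000380 to 0.816 over its alternatives. Among these, the call of Yme1l1 was lost without WT 2, WT 5, TG 2, TG 3 or TG 5 (adjusted p 0.05003 to 0.0899), that of Htra2 without WT 2, WT 5, TG 1, TG 2 or TG 3 (0.0511 to 0.0906) and that of Bnip3 without TG 2, TG 3 or TG 5 (0.0517 to 0.0633). Lists with genes in both directions and no call by camera were creatine and calcium cycling, branched-chain amino acid breakdown, mitophagy and autophagy, antioxidant, interferon, cytokine, cholesterol synthesis and clock genes, at adjusted p values of 0.369, 0.161, 0.878, 0.136, 0.970, 0.596, 0.146 and 0.414. Median, mean and test differed in sign for the creatine, integrated stress response and interferon lists. Adjusted over the list alone, 18 immediate early genes, 17 of the cytosolic ribosome, 11 of mitophagy and 12 cytokine genes were lower, 4 interferon genes and 1 cell cycle gene were higher, and the other counts given here were the same. Cell cycle genes had 2 of 9 higher (Mcm4 and Mcm7) and 7 not passing (adjusted p = 0.638), and the call of Mcm7 was lost without WT 2, WT 3, WT 5, TG 1, TG 2 or TG 5 (0.0615 to 0.116).

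Neutrophil markers had 4 of 5 lower (S100a8, S100a9, Csf3r and Retnlg) and 1 higher (Mmp9) but no call (camera adjusted p = 0.281); S100a8 fell by 3.13 with overlapping groups, and its call was lost without TG 2 (adjusted p = 0.0541) or TG 3 (0.0558), as was that of S100a9 without WT 3, TG 2 or TG 3 (0.0517 to 0.0579) and that of Retnlg without WT 2 and TG 5 (0.0563). The list itself was called with no filter (adjusted p = 0.0319). Mast cell (adjusted p = 0.820), Schwann cell (0.530) and lymphatic endothelial (0.399) markers were not called; S100b fell by 3.91. The 4 genes of the Y chromosome did not pass the test (camera adjusted p = 0.924) and the Xist gene had 0 reads in WT and 1 read in TG. Mesothelial and epithelial markers were below the filter and were not tested as a list.

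The mitochondrial ribosomal RNAs fell in TG, by a log2 change of -4.96 for mt-Rnr1 and -5.00 for mt-Rnr2. Both lay beyond the lowest of the 13 messenger RNAs, mt-Co3 at -4.58, whose value is uncertain because it has a nuclear copy. The 8 messenger RNAs with no copy of 100 FPKM or more had a median of -2.26. These differences were not tested. Nuclear copies were sought for the messenger RNAs alone, so reads shared with copies of the ribosomal RNAs were not tested. mt-Rnr1 went from 23080 ± 6526 to 724 ± 124 FPKM and mt-Rnr2 from 22830 ± 7738 to 686 ± 110 FPKM (SD, n = 4 each). One hypothesis is less RNA without a poly(A) tail in the TG libraries. The test asked for a fall among nuclear RNAs without a tail, but only 1 nuclear RNA without a poly(A) tail, a small nucleolar RNA, reached a mean of 20 recovered reads (22.75); its log2 change with a pseudocount of 0.1 was -1.64, in the direction the hypothesis needs, but a single RNA is too few to decide, so library content and a change in the tissue cannot be told apart for these RNAs.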
